A study of Mus musculus with 12 samples.

How the data were processed

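Total RNA from mouse ileum tumours was measured on Illumina bead arrays, 1 array per tumour sample, in 12 samples from FVB/N mice aged 3 to 4 months. The labels give 6 arrays to the genotype FVBN/APCmin (replicates 1 to 6) and 6 to iPGC-1β/APCmin (replicates 7 to 12). RNA was extracted with Qiazol, checked by Experion electrophoresis and labelled with biotin. Nothing in the labels says whether the tumours came from separate animals, so each p-value below measures the spread between these samples. The labels give no chip, array position or date for any sample.

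The deposited unnormalized table holds, per the file headers, an average signal intensity for each of 25697 probes on each array. Its column medians differ between arrays, and it was read as linear intensity without background subtraction. The same table gives, per the file headers, a detection p-value for each probe on each array, measured against the negative controls of that array. A second deposited table holds linear intensity that the authors had quantile-normalized without background subtraction, as read from its values: all its columns have medians of 157.8 to 158.1. Values of the same sample in both tables correlated at 0.9989 to 0.99996 across probes. GenomeStudio is named in the submitters' processing notes, with no version given.

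Unnormalized intensities were processed in R 4.3.3 with limma 3.58.1. The function neqc corrected the background by a normal-exponential model with control statistics inferred from the detection p-values, added an offset of 16, quantile-normalized the arrays and took log2. Probes with a detection p-value below 0.05 on at least 4 of the 12 arrays were kept (14827 probes). Where several kept probes shared a symbol, the probe with the highest mean was used, which left 10967 genes. The 69 other kept probes of the genes named by the rule below all differed in the same direction as the probe used, that of Bcl2l2 by as little as 0.00011. Other probes of genes chosen outside the rule were not compared. Of the 18138 symbols in the table, 14307 equalled a current mouse gene symbol and 2906 matched through a synonym. The 31 probes whose symbol had become a spreadsheet date were kept under their probe identifiers. No probe coordinates were used.

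The design holds a single comparison, iPGC-1β/APCmin minus FVBN/APCmin. It was tested with limma (lmFit, then eBayes with an intensity trend) and a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Ppargc1b was also tested with an exact two-sided permutation test of the difference in means over all 924 relabelings of the 12 arrays. The smallest p this test can give is 0.0022. The number of arrays limits the precision of all values. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 45 lists. Camera with an estimated correlation, limma's rotation test fry, and an exact permutation test of each list's mean level per array were set beside it. A list's level on an array is the mean of its genes after each gene was centred over the 12 arrays.

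The 45 lists were written from general knowledge of gene function and cell types. They cover mitochondrial and lipid metabolism, apoptosis, the cell cycle, Wnt signalling, cell types of the gut wall, blood and immune cells, stress responses and sex-linked genes. Of their 1042 entries, 953 were on the array, 42 of them under another symbol, and 812 were tested. Lists, tests, settings and the rule for naming genes were fixed before the data were examined. By that rule the named genes were Ppargc1b, the 12 genes past the threshold with the largest rise and the 12 with the largest fall, up to 4 genes with the smallest p in each list, and the sex-linked genes. Symbols that only number a locus or clone were left out of the rule. They made up 49 of the genes past the threshold, 35 higher and 14 lower. From lists that did not pass, fewer genes are given. Cd3e, Vegfa, Txn2, Bid, Cxcl9 and Esrra lie outside the rule and were chosen after their values were seen.

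Alternatives fixed in advance were a neqc offset of 50, no background correction, cyclic loess, a shift to a common 75th percentile, no filter, a filter at a detection p-value of 0.01 on 6 arrays, the mean of all kept probes of a gene, eBayes without trend, array quality weights, the authors' normalized table, a smooth muscle and fibroblast covariate, leaving out each array, a fold minimum of 1.5, all kept probes counted singly, camera with an estimated correlation, and fry. Chosen after the data were seen were covariates for the lymphocyte level, the Wnt target level and the raw intensity, leaving out arrays 6 and 7 together, the permutation test of list levels, the lymphocyte covariate combined with an estimated correlation, and tests of symbol families. So was the joint level of the 91 respiratory chain and TCA cycle genes. The fits were also tested on simulated data with 10967 genes and 200 changed genes, in 10 runs. They recovered 6% of changes of 0.5 on the log2 scale, 45.8% of changes of 1 and 90% of changes of 2, and 4.72% of the genes passing were unchanged ones. In 10 simulated runs without any change, 0 lists passed camera. The simulated genes varied independently of each other, whereas genes on these arrays moved together. Neither the shares of genes nor the count of lists therefore carries over to these arrays. Here 100 splits of the samples passed 7 to 25 lists each, and a split other than the real one passed 284 genes.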

Results

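Gene expression was measured in ileum tumours of APCmin mice, which carry a truncating mutation of the tumour suppressor gene Apc and develop intestinal adenomas. The 12 arrays fell into 6 labelled FVBN/APCmin and 6 labelled iPGC-1β/APCmin. The latter name stands for mice with extra PGC-1β in the intestine, although the labels do not describe the construct. PGC-1β, the product of Ppargc1b, is a coactivator of transcription that switches on mitochondrial genes. Median raw intensity per array ran from 139.3 to 170.5 (139.3 to 167.9 in FVBN/APCmin and 145.6 to 170.5 in iPGC-1β/APCmin). Between 12858 and 14445 probes were detected per array, with a median of 54.0% and at most 56.2% of the 25697 probes. Differences below are iPGC-1β/APCmin minus FVBN/APCmin on the log2 scale, with n = 6 arrays per group. Group means are given with the SD and differences with the standard error (SE).

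The comparison asked how tumours with extra PGC-1β differed in expression from tumours of the control genotype. The Ppargc1b probe itself was not higher in the arrays labelled iPGC-1β/APCmin. Its log2 level was 8.41 ± 0.65 (SD, n = 6) in FVBN/APCmin and 7.86 ± 0.44 (SD, n = 6) in iPGC-1β/APCmin. The difference was -0.55 (SE 0.30; limma adjusted p = 0.296; exact permutation p = 0.115), within the spread between arrays. On arrays 1 to 6 the log2 level of Ppargc1b was 8.80, 7.70, 8.22, 7.64, 9.17 and 8.94. On arrays 7 to 12 it was 7.15, 8.10, 7.68, 8.14, 8.38 and 7.73. The array held 1 probe for this gene, and where it lies relative to the transgene is not given in the sources used here. The measured level therefore did not show the genotype, and directions below follow the labels.

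Tumours labelled iPGC-1β/APCmin carried more mRNA for the mitochondrial machinery that burns fuel, and, on all of them except array 7, less mRNA from lymphocytes and for antigen presentation. Among the control tumours array 6 was also low in lymphocyte mRNA, and the lower immune lists did not pass by permutation. No list, mitochondrial ones included, passed with an estimated correlation. Genes of respiratory complex I, which feeds electrons from NADH into the respiratory chain, were higher by a mean of 1.07 on the log2 scale, and all 33 were higher. Sirt3, which encodes a deacetylase that activates mitochondrial enzymes, rose by 1.82 (SE 0.23, adjusted p = 0.00184), from 8.95 ± 0.10 to 10.76 ± 0.57 (SD, n = 6 each; limma). In the opposite direction, genes of T and NK cells were lower by a mean log2 difference of -1.48, and Fcmr, a receptor for IgM on lymphocytes, fell by 5.45 (SE 1.28, adjusted p = 0.0363). In all, 378 of 10967 genes passed the limma threshold, 243 higher and 135 lower. A fold of at least 1.5 was reached by 240 and 134 of them. All 6 arrays of a group lay beyond all 6 of the other for 167 of the higher and 52 of the lower genes. Among all genes tested 309 separated the groups this way, where chance gives 0.216% of genes. At an unadjusted p below 0.05 there were 2557 genes, against 548.4 expected by chance. Both chance figures are averages, and genes moved together between arrays, so a single split can lie far above them. The median difference over all genes was -0.01.

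**Figure D1:**
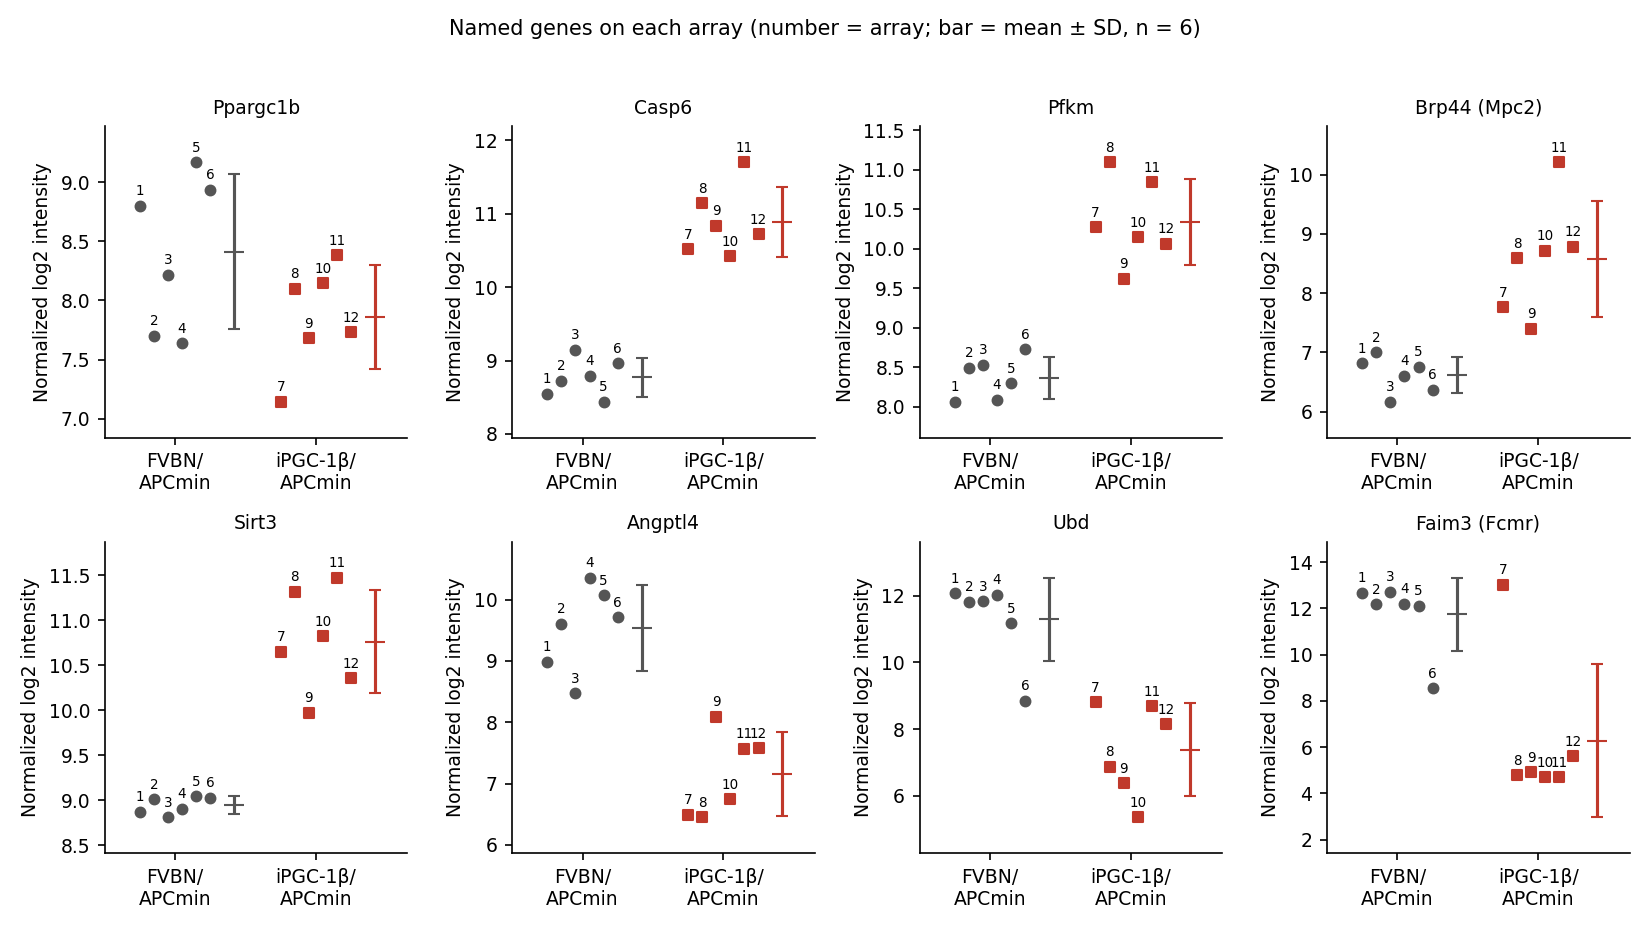
Log2 level on each array of Ppargc1b and of selected genes past the threshold, FVBN/APCmin (arrays 1 to 6) and iPGC-1β/APCmin (arrays 7 to 12), with group means and SD. Ppargc1b overlaps between the groups, Casp6 does not, and Faim3 (Fcmr) on array 7 lies with the FVBN/APCmin arrays.

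The 12 largest rises among genes with a name of their own follow. Casp6, which encodes an executioner protease of apoptosis, rose by 2.12 (SE 0.22, adjusted p = 0.000865), from 8.77 ± 0.26 to 10.89 ± 0.47 (SD, n = 6 each; limma). Pfkm, the muscle form of the glycolytic enzyme phosphofructokinase, rose by 1.97 (SE 0.24, adjusted p = 0.00132). Hk1, the hexokinase that opens glycolysis, rose by 1.83 (SE 0.29, adjusted p = 0.00549), and Mpc2 (Brp44 in the file), a subunit of the carrier that brings pyruvate into mitochondria, rose by 1.96 (SE 0.38, adjusted p = 0.0155). The calcium-binding S100a1 rose by 2.53, the pacemaker channel gene Hcn2 by 2.50, the aminoacylase gene Acy3 by 2.48 and the procollagen processing enhancer Pcolce by 2.40. These 8 genes were higher on all 6 iPGC-1β/APCmin arrays than on any FVBN/APCmin array. The others of the 12 largest rises were the meiotic cohesin gene Rec8 (2.79), the decoy death receptor Tnfrsf22 (2.12), the complex IV subunit Cox7a1 (2.10) and the Ras-like Rasl2-9 (1.97). Rec8 was above the FVBN/APCmin mean on 5 of the 6 iPGC-1β/APCmin arrays and the other genes on 6.

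The 12 largest falls among genes with a name of their own follow, of which only Ciita and Cd274 belong to a fixed list. Fcmr (Faim3 in the file) averaged 11.74 ± 1.58 in FVBN/APCmin and 6.29 ± 3.32 in iPGC-1β/APCmin (SD, n = 6 each). Il4i1, an amino acid oxidase of antigen-presenting cells and B cells, fell by 4.35 (SE 1.08, adjusted p = 0.0443). Ccr6, a chemokine receptor of gut lymphocytes, fell by 4.28 (SE 1.02, adjusted p = 0.0390). The signalling adaptor genes Dok3 and Lat fell by 3.06 and 2.65, the receptor gene Gpr171 by 2.46 and Ciita, the master regulator of MHC class II, by 2.45. Each of these 7 genes was below the FVBN/APCmin mean on 5 of the 6 iPGC-1β/APCmin arrays. Array 7 was the exception. Each of the 7 genes kept its call in only 2 of 12 fits that left out an array, those without array 6 or array 7. Ubd, a ubiquitin-like modifier induced by interferon, fell by 3.92 (SE 0.66, adjusted p = 0.00798) and was lower on all 6 iPGC-1β/APCmin arrays than on any FVBN/APCmin array. Cd274, which encodes the checkpoint ligand PD-L1, fell by 2.44 (SE 0.43, adjusted p = 0.00946). The protease inhibitor genes Serpina1b, Serpina1d and Serpina3h had differences of -3.34, -3.10 and -2.79. These last 4 genes were below the FVBN/APCmin mean on 6 of 6 arrays.

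The respiratory chain and the TCA cycle, which together oxidise acetyl groups and make ATP, were higher throughout. Here and below, a gene said to pass or not to pass did so over all genes tested unless the list alone is named. In complex I 13 of 33 genes passed over all genes tested and 31 adjusted over the list alone, all of them higher, led by Ndufv2 (1.14), Ndufa10 (0.88), Ndufc2 (1.41) and Ndufb5. The camera adjusted p was 2.24e-19, and the adjusted p = 0.387 with an estimated correlation. Complexes II and III had a mean difference of 0.80 with 4 of 10 genes passing (Sdhc 0.78, Sdhd 0.87, Cyc1 0.83, Cycs 0.82) and 10 adjusted over the list alone. Their camera adjusted p was 3.70e-08, and the adjusted p = 0.281 with an estimated correlation. Complex IV had a mean of 0.95, with 6 of 15 genes passing (Cox10 0.81, Cox17 1.45, Cox5a 0.73 and Cox5b 0.98 among them) and 14 adjusted over the list alone. For it the camera adjusted p was 1.62e-10, and the adjusted p = 0.387 with an estimated correlation. The TCA cycle had a mean of 0.73, with 11 of 21 genes passing (Fh1 0.96, Idh3a 1.11, Dld 1.01 and Sdhc among them) and 16 adjusted over the list alone. Its camera adjusted p was 2.98e-13, and the adjusted p = 0.281 with an estimated correlation. The mean level of each of these 4 lists was higher on all 6 iPGC-1β/APCmin arrays than on any FVBN/APCmin array. Each had an exact permutation p of 0.0022, the smallest that 924 relabelings can give, and 0.0244 after adjustment over the lists. In all but the TCA cycle list array 7 was the lowest iPGC-1β/APCmin array. For complex I the gap was narrow, with array 7 at -0.196 and array 2 at -0.224.

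Other mitochondrial lists moved the same way with fewer single genes past the threshold. None of them passed by exact permutation of list levels (adjusted p = 0.0812 for ATP synthase, 0.105 for the mitochondrial ribosome and 0.110 for fatty acid oxidation). ATP synthase, the enzyme that makes ATP from the proton gradient, had a mean of 0.70 with all 15 genes higher. Atp5f1 (0.86) and Atp5g3 (0.55) passed, and 10 did adjusted over the list alone (camera adjusted p = 5.02e-07, adjusted p = 0.387 with an estimated correlation). The mitochondrial ribosome, which translates the respiratory subunits encoded in mitochondrial DNA, had a mean of 0.64 with 68 of 69 genes higher. There 4 genes passed, Mrps2 (1.01), Mrpl47 (1.48), Mrps5 (1.17) and Mrpl37 (0.61), and 30 did adjusted over the list alone (camera adjusted p = 1.05e-15, adjusted p = 0.485 with an estimated correlation). Mitochondrial fatty acid oxidation had a mean of 0.31 with 18 of 22 genes higher. The 4 genes passing were Bdh1 (1.20), Echs1 (0.75), Acadvl (1.22) and Etfdh (1.04), and adjusted over the list alone 6 were higher and 1 lower (camera adjusted p = 0.00376, adjusted p = 0.580 with an estimated correlation). The first pair of lists was above the FVBN/APCmin mean on 6 of 6 iPGC-1β/APCmin arrays and fatty acid oxidation on 5. Ribosomal proteins of the cytosol did not move with them (mean -0.09 over 25 genes, camera adjusted p = 0.491, none passing).

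Regulators and partners of the PGC-1 family, which sit upstream of these genes, did not move as a list. Sirt3 and the mitochondrial transcription factor Tfb2m (0.72, adjusted p = 0.0388) rose, and the other 19 of 21 genes did not pass over all genes tested or adjusted over the list alone. Among these were Mef2c (-2.47, but 0.32 with the lymphocyte level as a covariate), Ncor1 (-0.64) and Esrra (0.61). The list's mean difference was -0.06 (0.08 with that covariate) while its median was 0.01 and its test pointed up (camera adjusted p = 0.776). Antioxidant defence did not pass as a list (mean 0.14 over 33 genes, camera adjusted p = 0.160). Of its members 5 did rise, the superoxide dismutase gene Sod2 by 0.99, the peroxiredoxin genes Prdx5 by 1.13, Prdx2 by 1.16, Prdx3 by 1.17 and the thioredoxin gene Txn2 by 0.94. These 5 also passed adjusted over the list alone, and the other 28 did not.

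**Figure D2:**
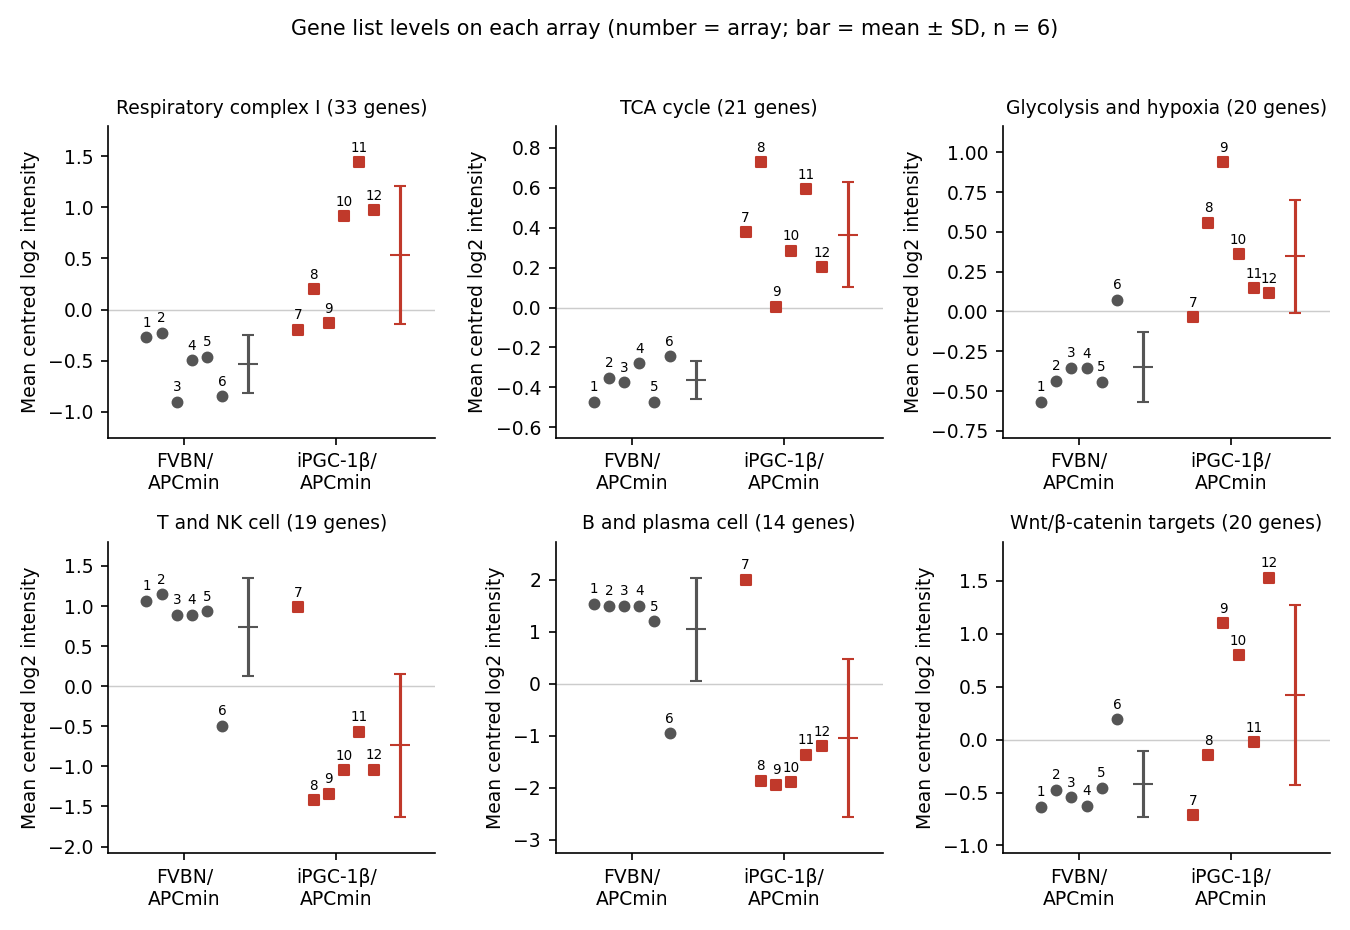
Mean log2 level per array of selected gene lists, each gene centred over the 12 arrays, FVBN/APCmin (arrays 1 to 6) and iPGC-1β/APCmin (arrays 7 to 12). Complex I separates the groups narrowly (array 7 at -0.196, array 2 at -0.224). The T and NK cell level of array 7 (0.98) lies with FVBN/APCmin and that of array 6 (-0.49) lies below the other FVBN/APCmin arrays.

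Glycolysis and hypoxia genes were higher by a mean of 0.69 (0.29 with the lymphocyte level as a covariate, camera adjusted p = 0.00501), with 19 of 20 genes higher and a level above the FVBN/APCmin mean on 6 of 6 arrays. Gapdh (0.91), Hk1, Aldoa (0.99), Pgam1 (1.09) and the angiogenic factor Vegfa (1.61) passed, and 11 genes did adjusted over the list alone. The camera adjusted p was 5.78e-09, the adjusted p = 0.387 with an estimated correlation, and the exact permutation p 0.00433 (0.0390 adjusted). Lipid pathways outside mitochondria did not pass. Peroxisomal oxidation and PPARα targets had a mean of -0.14 and a median of 0.05 (camera adjusted p = 0.718). In that list Angptl4, a secreted inhibitor of lipoprotein lipase, fell by 2.38 (adjusted p = 0.00511), lower on all 6 arrays than on any of the other group, and it alone passed adjusted over the list alone. Fatty acid and triglyceride synthesis had a mean of 0.15 and a median of -0.04 (camera adjusted p = 0.491). None of its 18 genes passed over all genes tested, and 1, Fads2 (0.71), did adjusted over the list alone. Cholesterol synthesis had a mean of -0.01 over 19 genes (camera adjusted p = 0.850), none passing.

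Lymphocyte genes differed between the groups with uneven arrays. The T and NK cell list was lower by a mean of -1.48 with 18 of 19 genes lower. Cd3e (-2.31) and Cd8b1 (-2.12) of the T cell surface, the checkpoint receptor Ctla4 (-1.76), and Klrd1 (-1.15) and Nkg7 (-1.71) of cytotoxic cells fell, and 16 genes passed adjusted over the list alone (camera adjusted p = 8.57e-10, adjusted p = 0.417 with an estimated correlation). B and plasma cell genes had a mean of -2.09 with 13 of 14 lower. None passed over all genes tested and 9 did adjusted over the list alone (camera adjusted p = 4.21e-06, adjusted p = 0.447 with an estimated correlation), with Fcrla (-3.58), Fcer2a (-3.13) and Cd79b (-3.78) among these 9. Both lists were below the FVBN/APCmin mean on 5 of 6 iPGC-1β/APCmin arrays. MHC class II, which presents antigen to T cells, was lower by a mean of -1.79 with 10 of 11 genes lower. H2-DMb1 (-1.88), H2-Ab1 (-2.12) and Ciita fell, H2-Ea (-2.90) did not pass, and 9 passed adjusted over the list alone (camera adjusted p = 3.77e-06, adjusted p = 0.417 with an estimated correlation). The interferon response had a mean of -0.61 with 19 of 26 genes lower. The guanosine triphosphatase genes Ifi47 (-1.89), Igtp (-2.27) and Gbp2 (-1.56) fell, as did Cd274 and Cxcl9 (-1.83), and adjusted over the list alone 9 were lower and 1 higher (camera adjusted p = 0.000311, adjusted p = 0.547 with an estimated correlation). Exact permutation of the levels of these 4 immune lists gave adjusted p-values of 0.0852, 0.110, 0.0835 and 0.105, none below 0.05.

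The lymphocyte level, the mean of both lymphocyte lists, lay between 1.05 and 1.29 on arrays 1 to 5 and between -1.61 and -0.91 on arrays 8 to 12. Array 6, labelled FVBN/APCmin, was at -0.69 and array 7, labelled iPGC-1β/APCmin, at 1.41, so both lay nearer to the other group. The mean of the complex I to IV, ATP synthase and TCA lists (91 genes) was -0.59 on array 6, within the -0.67 to -0.26 of arrays 1 to 5, and -0.05 on array 7, above them. Its group difference was 0.890 (95% confidence interval 0.445 to 1.33, exact permutation p = 0.0022). With the lymphocyte level as a covariate it was 0.784 (0.131 to 1.44). These 91 genes were joined after their lists were seen to differ, so that permutation p is not separate evidence. Across genes array 7 correlated at 0.952 to 0.971 with arrays 1 to 5 and at 0.852 to 0.892 with arrays 8 to 12. Array 6 correlated at 0.920 to 0.951 with the former and at 0.906 to 0.953 with the latter. Without array 7, 1821 genes passed, and with the lymphocyte level as a covariate 7 did, while 1170 had an unadjusted p below 0.05. Differences in the immune genes shrank with that covariate, from -4.35 to -0.57 for Il4i1, from -4.28 to -0.68 for Ccr6 and from -2.45 to -0.63 for Ciita. Casp6 stayed past the threshold, at 1.92 (adjusted p = 0.0406). Of the 19 lists passing camera, 11 passed with it too, 2 form the covariate and 6 no longer passed: Wnt targets, G1/S (-0.36 to -0.02), endothelial (0.60 to 0.15), neutrophil and mast cell (1.19 to 0.02), red blood cell (1.76 to 0.45) and MHC class II (-1.79 to -0.39). Another 8 passed only with it, all lower: smooth muscle (-0.11 to -1.01), epithelial identity (-0.16 to -0.55), goblet cell (-0.20 to -0.80), adipocyte (-0.14 to -0.82), enteric neuron and glia (0.01 to -0.56), xenobiotic metabolism (-0.20 to -0.45), cholesterol synthesis (-0.01 to -0.38) and endoplasmic reticulum stress (-0.17 to -0.25). None of these held with an estimated correlation.

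**Figure D3:**
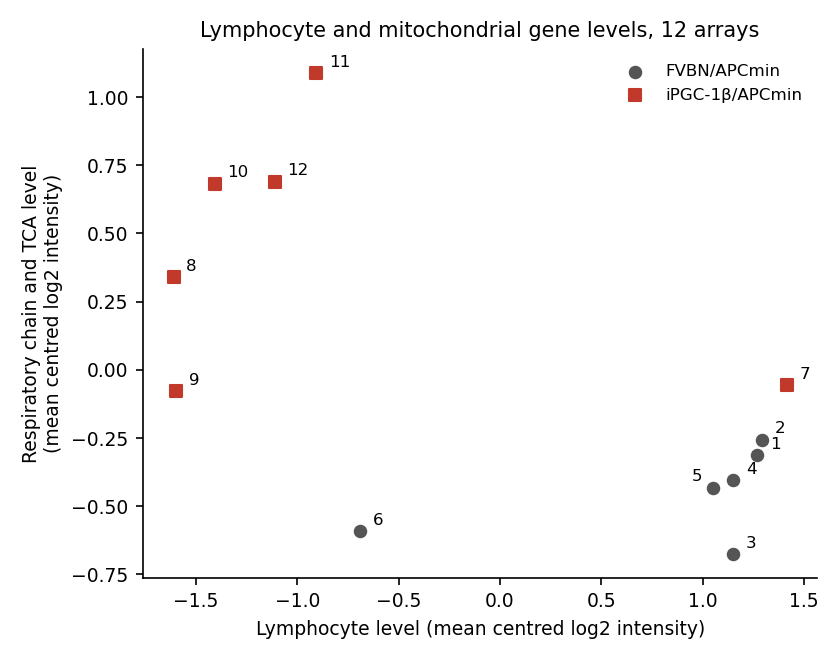
Mean log2 level of the 91 respiratory chain and TCA cycle genes against the lymphocyte level on each array, numbered 1 to 12, with genes centred over the arrays. Arrays 1 to 5 and 8 to 12 lie apart on both axes, array 6 has a lymphocyte level of -0.69 and array 7 one of 1.41.

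Lists of epithelial function were lower where they passed. Ileal bile acid handling, the recovery of bile acids at the end of the small intestine, had a mean of -0.71 with 8 of 9 genes lower and 6 of 6 iPGC-1β/APCmin arrays below the FVBN/APCmin mean. The bile acid receptor gene Nr1h4 (-1.04) and the exporter subunit Slc51a (Osta in the file, -1.27) fell, Slc51b (Ostb, -1.29) and Fabp6 (-1.46) did not pass, and 4 passed adjusted over the list alone (camera adjusted p = 0.0105, adjusted p = 0.447 with an estimated correlation). Enterocyte genes, of the absorptive cell, had a mean of -0.39 with 18 of 24 lower and 5 of 6 arrays below. The peptidase gene Enpep (-1.19) fell, Anpep (-1.60) and Mep1b (-0.86) did not pass, and 2 passed adjusted over the list alone (camera adjusted p = 0.00841, adjusted p = 0.699 with an estimated correlation). The list did not pass without array 6 (-0.32) or without array 9 (-0.22). Wnt targets, which report the pathway that Apc restrains, had a mean of 0.85 with 18 of 20 higher and 5 of 6 arrays above. None passed over all genes tested and 4 did adjusted over the list alone (camera adjusted p = 0.000226, adjusted p = 0.550 with an estimated correlation). The Wnt inhibitor genes Notum (3.13, SE 0.91, adjusted p = 0.0677) and Apcdd1 (1.64), and the transcription factor genes Sox9 (1.47) and Sp5 (1.56), did not pass. With the lymphocyte level as a covariate the mean of the Wnt targets was 0.07 (camera adjusted p = 0.661). Array 6 had a Wnt target level of 0.19, above the -0.63 to -0.45 of arrays 1 to 5.

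Other epithelial lists did not pass and held no gene past the threshold over all genes tested. Their mean differences were 0.16 for intestinal stem cells (Lgr5 1.03), -0.16 for epithelial identity (Cdx1 -0.69), -0.20 for goblet cells (Gfi1 -0.87), 0.40 for Paneth cells (10 of 11 genes higher, Lyz2 the exception at -1.98) and 0.47 for tuft cells (Avil 2.41). The camera adjusted p-values were 0.462, 0.187, 0.510, 0.160 and 0.340. Adjusted over the list alone 1 tuft cell gene passed and none in the others. The enteroendocrine list had a mean of -0.02 while its test pointed up (camera adjusted p = 0.956, Gcg -1.01 not passing).

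Genes of the G1/S transition, when DNA replication begins, had a mean of -0.36 with 21 of 25 lower and 4 of 6 arrays below the FVBN/APCmin mean (camera adjusted p = 0.00875, adjusted p = 0.699 with an estimated correlation), and the list did not pass without array 8 (-0.22). Of these the S phase regulator E2f2 (-1.33) fell, Ccnd2 (-1.18), Mcm6 (-0.77) and Mcm5 (-0.96) did not pass, and 2 passed adjusted over the list alone. Mitotic G2/M genes had a mean of -0.19 (camera adjusted p = 0.187) and none of 20 passed. The pro-apoptotic list had a mean of -0.02 (camera adjusted p = 0.776) with members moving both ways. Casp6 and Aifm1 (0.87), which encodes a mitochondrial flavoprotein, rose, while the death receptor Fas (-1.45), the initiator Casp8 (-0.74) and Bid (-1.19) of the same pathway fell, and the same 2 and 3 genes passed adjusted over the list alone. None of the 11 anti-apoptotic genes passed (mean -0.15, camera adjusted p = 0.601, Birc3 -0.82). Endoplasmic reticulum stress had a mean of -0.17 (camera adjusted p = 0.0988). In it Xbp1 (-0.65), the transcription factor of the secretory response, and Edem1 (-1.13) fell, lower on all 6 arrays, and 3 genes passed adjusted over the list alone.

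Blood and vessel lists were higher without any gene past the threshold over all genes tested. Neutrophil and mast cell genes had a mean of 1.19 with 10 of 11 higher (camera adjusted p = 0.00376, adjusted p = 0.547 with an estimated correlation), and 1 passed adjusted over the list alone, with Ltf (3.02) and Cpa3 (1.57) not passing over all genes. Endothelial genes had a mean of 0.60 with 16 of 20 higher (camera adjusted p = 0.00120, adjusted p = 0.547 with an estimated correlation), and 7 passed adjusted over the list alone. Cdh5, the endothelial cadherin, was detected on none of the FVBN/APCmin arrays and on 5 of the other group, which makes it at least 1.30-fold higher, without passing. The 4 red blood cell genes had a mean of 1.76 (camera adjusted p = 0.0212, adjusted p = 0.547 with an estimated correlation), and 2 passed adjusted over the list alone, with Hba-a1 (2.58) not passing over all genes. Without array 9 (1.24) this list did not pass. These 3 lists were above the FVBN/APCmin mean on 5 of 6 arrays.

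The remaining lists did not pass camera. Macrophage and dendritic cells had a mean of -0.42 (adjusted p = 0.0627), with the protease gene Ctss (-0.69) falling and 1 gene passing adjusted over the list alone. Inflammatory cytokines and chemokines had a mean of 0.02 while their test pointed down (adjusted p = 0.607). There Nos2 (-1.75), the inducible nitric oxide synthase, fell on all 6 arrays, and 5 genes were lower adjusted over the list alone. No gene passed over all genes tested in fibroblast and extracellular matrix (mean 0.12, adjusted p = 0.590), smooth muscle (-0.11, 0.607), enteric neuron and glia (mean 0.01, median -0.03, 0.956), pancreas (1.09, 0.195), adipocyte (-0.14, 0.607, with 1 gene passing adjusted over the list alone), xenobiotic metabolism (-0.20, 0.160) or immediate early and heat shock genes (0.26, 0.323). The sex-linked list did not differ (mean -0.14, adjusted p = 0.607), with Ddx3y at -0.49, Uty at 0.24, Kdm5d (Jarid1d) at -0.25 and Eif2s3y at -0.05, none passing. At least 1 probe each for Ddx3y, Eif2s3y and Uty was detected on all 12 arrays, the 2 other Ddx3y probes on 2 arrays each, and the 2 Xist probes on 0 and 1 of them.

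In total camera passed 19 of 45 lists, 12 higher and 7 lower, fry passed 9 (6 higher and 3 lower), permutation passed 5, all higher, and camera with an estimated correlation passed 0 (smallest adjusted p = 0.281). Genes within the 19 lists moved together between arrays, with estimated correlations of 0.205 to 0.801.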

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

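The tests with the lymphocyte, Wnt target and raw intensity levels as covariates, the relabelling of arrays 6 and 7 and the placing of the Ppargc1b probe were chosen only after the results were seen.

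Within each group of 6 arrays, 25 results had a single array far from the rest, measured as its gap to the nearest other array divided by the whole range of the group. Chance gives such an array in about 1 in 20 groups, or 7 of the 140 sets examined, but sets that share genes are not independent. All 25 concerned array 6 (17) or array 7 (8). Array 6 was the lowest FVBN/APCmin array in T and NK cell genes (0.845) and B and plasma cell genes (0.866), and in Faim3 (Fcmr, 0.856), Il4i1 (0.785), Ccr6 (0.833), Ubd (0.724), Serpina1b (0.682), Serpina1d (0.643), Dok3 (0.825), Lat (0.793) and Gpr171 (0.754). It was the highest in Wnt targets (0.783), Paneth cell genes (0.764), neutrophil and mast cell genes (0.701), pancreas genes (0.812), glycolysis and hypoxia genes (0.667) and Tnfrsf22 (0.758). Array 7 was the highest iPGC-1β/APCmin array in T and NK cell genes (0.646), B and plasma cell genes (0.812), Faim3 (0.890), Il4i1 (0.958), Ccr6 (0.775), Dok3 (0.719), Gpr171 (0.654) and Cd274 (0.794).

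Lymphoid tissue, such as a Peyer's patch taken along with a tumour, may have contributed to the genes lower in iPGC-1β/APCmin. With the lymphocyte level as a covariate, 26.2% of the 130 lower genes outside the lymphocyte lists lost most of their difference, with a median ratio to the unadjusted value of 0.772, so this source stays open. Of the 243 higher genes 4.53% lost as much, with a median ratio of 0.912, and 3 still passed, with errors 1.39 times as large. Genes that follow the lymphocyte level tend not to pass with arrays 6 and 7 under their labels (0 of 14 B and plasma cell genes did). The low share among passing genes is thus partly set by their selection, and lymphoid tissue stays open for the higher genes too. A larger share of adenoma tissue, as the higher Wnt targets would give, also stays open as a source of the lower genes. With the Wnt target level as a covariate 4.44% of 135 lost most of their difference. The median ratio was 0.758, with errors 1.11 times as large, and 22 of the 135 still passed. The same kind of selection limits this test, since 0 of 20 Wnt targets passed over all genes tested. A change in lymphocytes that belongs to the genotype stays open and untested, because lymphocyte genes and genotype move together on 10 of the 12 arrays.

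Higher respiratory chain and TCA cycle genes are consistent with more PGC-1β activity, but the design gives no test of that cause. The difference of 0.890 was 0.784 (95% confidence interval 0.131 to 1.44) with the lymphocyte level as a covariate. With the Wnt target level it was 0.841 (0.258 to 1.42). Both fits rest largely on arrays 6 and 7, where these levels part from the genotype and whose labels are not settled. The 91 genes were also taken after they were seen to differ under those labels. Lymphoid tissue and the share of adenoma tissue therefore stay open, as the whole cause or as a part. Array brightness is argued against as the whole cause by 0.893 (0.447 to 1.34) with the raw intensity. Cytosolic ribosome genes did not differ by the same measure (-0.09, interval -0.736 to 0.553). Other differences in cell make-up between the tumours stay open.

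The Ppargc1b probe was not higher in iPGC-1β/APCmin, and relabelling gave no clear rise: its difference was 0.05 (95% confidence interval -0.764 to 0.864) with arrays 6 and 7 exchanged and -0.22 (-1.03 to 0.588) with array 7 counted as FVBN/APCmin. By the level of the 91 mitochondrial genes, 2 of the 2 arrays lay within the range of the other arrays of their own label. Array 7 (-0.055) did so only through array 9 (-0.078), since arrays 8 and 10 to 12 lay at 0.341 or above. Array 6 had a gap of 0.513 to the other group's range and array 7 one of 0.201. These genes were taken for this check after they were seen to differ between the labelled groups, so it cannot decide on an exchange. Gene by gene, 53 of the 91 (58.2%) placed array 7 nearer to FVBN/APCmin and 5 placed array 6 nearer to iPGC-1β/APCmin, and of the 2183 genes passing without both arrays, which include the lymphocyte genes, 79.4% and 57.5% did. Neither an exchange nor the label of array 7 alone is thus settled. The probe may also lie outside the sequence carried by the transgene, which cannot be told apart here because the 1 probe was not placed on either sequence.

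For the count of 378 genes, 100 splits of the 12 arrays into 6 and 6 were drawn, the real one included. Of these 1, the real one, gave as many, and the highest other split gave 284. The draw left out the exchange of arrays 6 and 7 given below, which passed more genes, so chance is not excluded. For the 19 lists passing camera chance cannot be excluded: 24 of 100 splits gave as many, and the highest other split gave 25. Exchanging the labels of arrays 6 and 7, a split outside this draw, gave 1939 genes and 21 lists. The lymphocyte level and the Wnt target level both divide the arrays as this split does. A wrong label of these arrays was not told apart from such a structure of the samples.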

How the results depend on the processing

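Settings chosen after the results were seen were the lymphocyte, Wnt target and raw intensity covariates, leaving out arrays 6 and 7 together, permutation of list levels and the lymphocyte covariate with an estimated correlation. The 378 genes (243 higher, 135 lower) became 200 (130 and 70) without a filter, where more genes were tested, 2403 (1192 and 1211) with array quality weights, 788 (371 and 417) with the smooth muscle and fibroblast covariate, 2183 (1055 and 1128) without arrays 6 and 7, 211 (39 lower) with the Wnt target covariate and 7 (3 and 4) with the lymphocyte covariate. Lower genes numbered 89 with the 75th percentile shift. The other settings gave 288 (the 75th percentile shift) to 459 (all kept probes counted) in total. Of the 378, 6 remained with the lymphocyte covariate, 148 with the Wnt target covariate and all 378 without arrays 6 and 7. With the lymphocyte covariate the median error of all genes was 1.36 times as large, although it shrank for some genes (Faim3 from 1.28 to 0.501). Leaving out 1 array gave 128 (without array 3) to 1821 (without array 7) genes, 92 to 848 higher, 35 (without array 1) to 973 lower, and 19 to 23 lists. Totals were 138, 157, 128, 169, 145 and 728 without arrays 1 to 6 in turn, and 1821, 420, 403, 188, 167 and 247 without arrays 7 to 12. Lists fell from 19 to 9 with fry, 5 by permutation, and 0 with an estimated correlation, alone or with the lymphocyte covariate. An estimated correlation weakens the test where genes within lists move together, as they did here. With the lymphocyte covariate 13 of 43 lists changed direction, 2 of them past the threshold with or without it: neutrophil and mast cell genes, whose test pointed down beside a mean of 0.018, and enteric neuron and glia at -0.56. Apart from the construction of each fit, the cause was not tested. Ppargc1b stayed negative and short of the threshold in every setting, -0.70 (without array 4) to -0.40 (without array 5) when 1 array was left out, -0.30 without arrays 6 and 7 and -1.08 with the lymphocyte covariate. Faim3, Il4i1, Ccr6, Dok3, Lat, Gpr171 and Ciita kept their call in 2 of 12 fits that left out an array (array 6 or array 7), Rec8, Tnfrsf22 and Cox7a1 in 3, Serpina3h in 7, Rasl2-9 in 11 and the other 12 named genes past the threshold in all 12. Of the 19 lists, enterocyte (-0.61 without array 8; not passing without array 6, -0.32, or array 9, -0.22), G1/S (not passing without array 8, -0.22) and red blood cell (not passing without array 9, 1.24) lost their call in such fits. No paired analysis was possible because the groups share no replicate numbers. A chip block was not run because the headers name no chip, nor an Xist covariate because the arrays showed a single sex. Lists that form a covariate have no value under it. Signal near background limits dim genes such as Cdh5.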

Other observations

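Genes and families in this part were chosen, and all its tests run, only after the results were seen.

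The largest rise of all 378 genes was in Aspdh (0610012D14Rik in the file), an aspartate dehydrogenase-like gene whose clone name kept it out of the naming rule. It rose by 4.50 (SE 0.47, adjusted p = 0.000865 by limma), from 4.62 ± 0.15 to 9.12 ± 1.30 (SD), and was higher on all 6 iPGC-1β/APCmin arrays. The FVBN/APCmin mean of 4.62 lies near background, below the 4.78 of Cdh5, which was detected on none of those arrays. The size of the rise is therefore uncertain. Other genes outside the fixed lists, singled out for their mitochondrial function, were as follows. The permeability transition regulator Ppif rose by 1.32, the mitochondrial carrier Slc25a39 by 1.66, the fission factor Mff by 1.56, the nucleotide carrier Slc25a4 by 1.42, the import channel subunit Timm17a by 1.15, the elongation factors Gfm1 and Tufm by 1.39 and 0.87, and the mitochondrial RNA-binding Fastk by 1.37. Each of these was higher on all 6 arrays. With the lymphocyte level as a covariate 7 genes passed: Ppif (1.57), Aspdh (4.68) and Casp6 (1.92) higher, and the secreted antagonist Nbl1 (-1.74), Sh3d21 (-1.74), Susd2 (-2.88) and the carboxylesterase Ces1f (AU018778, -2.13) lower.

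Further genes singled out among those that fell form no tested group. The inflammatory caspases Casp1 and Casp4 fell by 0.89 and 1.70, the pore-forming Gsdme (Dfna5h) by 1.92 and the release channel Panx1 by 1.56. The tryptophan-degrading Ido1 (Indo) fell by 2.30 and the efflux pump Abcg2 by 1.36. Of these 6 genes all but Casp4 were lower on all 6 arrays. With the lymphocyte covariate the differences were -0.64 for Casp1, -0.74 for Casp4, -1.81 for Gsdme, -1.28 for Panx1, -1.99 for Ido1 and -1.42 for Abcg2, none past the threshold.

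Of 119 families of genes that share the letters of their symbol and have at least 10 members tested, 12 passed camera, none by permutation (smallest adjusted p = 0.110) and none with an estimated correlation (smallest adjusted p = 0.794). The serpin family Serpina had a mean of -1.53 over 10 genes, 4 of them past the threshold, all lower. Import genes of the Timm family had a mean of 0.60 over 10 genes, and mitochondrial carriers of the Slc25a family 0.28 over 33, with 3 higher and 1 lower past the threshold. Families that repeat the fixed lists were Mrpl (0.64), Mrps (0.60), Cox (0.84), Ndufa (1.03) and Ndufb (1.20), all higher. Lower were Cd (-0.94), H (-0.66), Irf (-0.72) and Chst (-0.79).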
